A study of Mus musculus with 15 samples.

How the data were processed

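RNA-seq was performed on RPE/choroid complex from mouse eyes, with 7 control and 8 INK-ATTAC libraries. Per the labels' protocols, tissue was collected in TRIzol, RNA was purified on NucleoSpin columns and cDNA was amplified with SMARTer chemistry. Per the submitters' processing notes, the tools were bcl2fastq, DRAGEN, edgeR and limma and the genome build was GRCm38. Their versions, the counting program, its strand setting and the annotation release are not given in the sources used here. Without strand, reads of a gene and of an antisense or overlapping gene cannot be told apart, and reads of a pseudogene can be shared with its parent.

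The authors deposited a table of raw read counts per Ensembl gene, with 1 column per library, and per the file headers these counts are not normalized. It held 40757 entries, and 276 repeats of a gene with identical counts were collapsed, leaving 40481 genes. Gene symbols and gene types came with that table. Positions came from a GENCODE annotation of GRCm38, which held 17983 of the 17991 genes tested. The authors also deposited a comparison table of 14491 entries (14442 genes) with, per the file headers, log2 CPM per library, log2 fold change, confidence limits, p-value and adjusted p-value. The log2 CPM values in the authors' deposited table differed from limma-voom log2 CPM computed from the counts on TMM library sizes by a constant per library, between -0.0013 and -0.00045. Every gene in the authors' deposited table was over 1 CPM in at least 7 libraries. A refit with limma-voom and sample quality weights on such genes gave fold changes that correlated at 0.999 with those of the authors' deposited table across genes, and called 3 genes. Adjusted p-values in the authors' deposited table correspond to 14511 tests, more than its entries, and were used as deposited.

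Libraries were assigned to groups from their labels. Libraries of the same group were compared pairwise before averaging. The lowest chi-square value per gene of any such pair was 30.3, so no library repeated another of its group. Counts were scaled with TMM in edgeR 4.0.16 (R 4.3.3), and genes were kept with filterByExpr at its default settings, which left 17991 genes. The main test was edgeR's quasi-likelihood F-test for INK-ATTAC against control with no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error (SE) of an edgeR log2 fold change was derived as its absolute value over the square root of its F statistic. Mean CPM and SD are on TMM library sizes. The design also called for an edgeR fold change of Cdkn2a, but the gene did not pass the filter, so its counts per library and the pooled count ratio with an exact 95% interval are given in its place. SMARTer libraries without molecular identifiers hold amplified copies, so intervals and the floor of 3 counts for a count of 0 cover counting error only.

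Gene lists for pathways, cell types and RNA quality were written before the data were examined. 51 lists were written and 50 had at least 5 tested genes. They were tested with limma 3.58.1, camera with a preset correlation of 0.01 on voom log2 CPM, and again with an estimated correlation, with fry and with an exact permutation test of the mean level over all 6435 splits of the libraries into 7 and 8. Results of the lists nearest to the study and of all that passed are given. Correlations between list levels used 100000 permutations.

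Genes were named by a rule set before the data were examined. It took the 6 genes of the study's design, 5 sex-linked transcripts, the 12 genes with the largest change in each direction past the threshold with a mean log2 CPM of at least 1, and up to 4 members of lowest p of each list described. With fewer than 5 genes past the threshold in a direction, the 5 of lowest p took their place. Genes of predicted or clone-based name were left out of that rule.

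Alternatives set before the data were examined were DESeq2 1.42.0, RLE scaling, no low-count filter or CPM above 1 in 7 libraries, limma-voom with and without sample quality weights, glmTreat against a fold of 1.2, an adjusted p under 0.10, 1 surrogate variable (sva 3.50.0), covariates for rod, skeletal muscle and sex-linked level, a block by the number in the labels, and leaving out each library. Covariates for lens and endothelial level, and the rod, muscle and lens levels together, were chosen after seeing the data. Also chosen then were libraries of high or of low Xist alone, robust estimation, and quality weights with the stricter filter. For the lists the sex-linked covariate was chosen then too. So was a test of whether the group difference of a list or gene differed between libraries of low and high Xist, in which group labels were permuted within each class over all 2450 arrangements and p was adjusted over 30 lists and genes.

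The gene tests were tested on simulated data made from the means and library sizes of these libraries, with 200 of 17991 genes changed in each of 5 runs. For a 2-fold change edgeR recovered 69.2% of changed genes, for a 3-fold change 90.8%, for a 1.5-fold change 43.2% and for a 1.2-fold change 4%. Of 540 genes called, 4.07% were false. limma camera recovered 23 of 25 lists shifted by 1.2-fold and called 0 of 199 unshifted lists. Simulated genes varied independently, so this says nothing of lists whose genes vary together between libraries.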

Results

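RNA was sequenced from the mouse RPE/choroid complex, the retinal pigment epithelium (RPE) together with the vascular choroid that lies beneath it. The mice carried floxed alleles of Abca1 and Abcg1, which encode cholesterol efflux transporters, and LysM-Cre, a Cre recombinase expressed from the Lyz2 gene in myeloid cells, and the series concerns mice with drusenoid deposits under the retina. In 8 libraries the mice also carried INK-ATTAC, a transgene that places a fusion of FKBP and caspase 8 under the promoter of p16Ink4a, a cell cycle inhibitor found in senescent cells. The dimerizing drug AP20187 activates the fusion protein and so kills cells that use this promoter. The other 7 libraries came from mice without the transgene and serve as controls. All 15 libraries are labelled as AP20187 given into the peritoneal cavity, and for the INK-ATTAC mice the submitters describe dosing on alternate days over 3 months. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these samples.

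Total counts per library ranged from 39121503 in control 4 to 65065950 in INK-ATTAC 6. They averaged 49911319 ± 6938358 in controls (SD, n = 7) and 51901923 ± 5784427 in INK-ATTAC libraries (SD, n = 8), a difference within the spread (two-sided exact permutation test, p = 0.563). Mitochondrially encoded transcripts made up 2.79 ± 0.51% of counts in controls (SD, n = 7) and 2.55 ± 0.15% in INK-ATTAC libraries (SD, n = 8; exact permutation test, p = 0.274). Log2 CPM of the libraries correlated pairwise at 0.960 to 0.983 across genes, and no pair of the same group agreed within sampling noise. Xist, the noncoding RNA of the inactive X chromosome, was high and Y-linked transcripts low in 4 of the 7 control and 4 of the 8 INK-ATTAC libraries, and the pattern was the opposite in the others. The log2 fold change between groups, always given here as INK-ATTAC against control, was -0.15 for Xist, 0.28 for Ddx3y, 0.38 for Eif2s3y, 0.31 for Kdm5d and 0.28 for Uty, each with an adjusted p of 1.00.

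The first question was whether the transcripts tied to the ablation and to the floxed genes differed. Cdkn2a, the gene that encodes p16Ink4a and the overlapping protein Arf, was near the limit of detection in both groups. Its counts in controls 1 to 7 were 2, 0, 0, 2, 1, 2 and 0. In INK-ATTAC libraries 1 to 8 they were 4, 0, 1, 0, 0, 0, 0 and 1. Relative to total counts, the pooled INK-ATTAC to control ratio of these 6 against 7 counts was 0.721, with a 95% interval of 0.2003 to 2.51 that covers counting error only (exact binomial test, p = 0.589). A difference in Cdkn2a was therefore not detectable at this depth, and 3 control and 5 INK-ATTAC libraries held a count of 0, which allows up to 3 counts in each. INK-ATTAC 1 held 4 of the 6 counts in its group, and without it the pooled log2 ratio went from -0.47 to -1.88.

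Casp8 and Fkbp1a, the endogenous relatives of the transgene's parts, differed between the groups by less than the spread between libraries. Casp8 averaged 24.7 ± 1.93 CPM in controls (SD, n = 7) and 24.2 ± 3.01 CPM in INK-ATTAC libraries (SD, n = 8), a log2 fold change of -0.03 (SE 0.08). Fkbp1a averaged 238 ± 20.03 and 252 ± 16.7 CPM in the respective groups (log2 fold change 0.08, SE 0.06). Abca1 gave a log2 fold change of -0.06 (SE 0.12), Abcg1 of -0.13 (SE 0.22) and Lyz2 of -0.16 (SE 0.10). None of these 5 genes passed the edgeR test (adjusted p = 1.00 for each). The direction of all 5 turned in at least one other setting, so no direction is drawn from them.

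Across the 17991 genes tested, the genes with the lowest p were lower Ptgs2, Cxcl1 and Acp1 and higher Adi1 in INK-ATTAC libraries, but none passed the threshold. Ptgs2, the inducible cyclooxygenase that starts prostaglandin synthesis, averaged 4.11 ± 0.75 CPM in controls (SD, n = 7) and 2.06 ± 0.68 CPM in INK-ATTAC libraries (SD, n = 8), a log2 fold change of -0.999 (SE 0.20, adjusted p = 0.515). Cxcl1, a neutrophil-attracting chemokine, averaged 6.31 ± 2.02 and 2.78 ± 1.03 CPM (log2 fold change -1.18, SE 0.24, adjusted p = 0.546). Acp1, a low molecular weight protein tyrosine phosphatase, averaged 82.5 ± 8.85 and 62.5 ± 6.06 CPM (log2 fold change -0.40, SE 0.08, adjusted p = 0.515), and its control and INK-ATTAC libraries did not overlap. Adi1, an enzyme of the methionine salvage pathway, averaged 95.4 ± 9.33 CPM in controls and 122 ± 9.57 CPM in INK-ATTAC libraries (log2 fold change 0.36, SE 0.07, adjusted p = 0.515). Among genes with a mean log2 CPM of at least 1, and leaving out predicted or clone-based names, the next by p on the lower side were Cytip (log2 fold change -0.53, SE 0.13) and Togaram1 (-0.33, SE 0.08). On the higher side they were Eipr1 (0.29, SE 0.06), Gamt (0.39, SE 0.09), Mrps11 (0.22, SE 0.06) and Cmpk2 (0.43, SE 0.12). The control and INK-ATTAC ranges did not overlap for 4 genes, or 0.0222% of those tested, where chance gives 0.0311%.

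**Figure D1:**
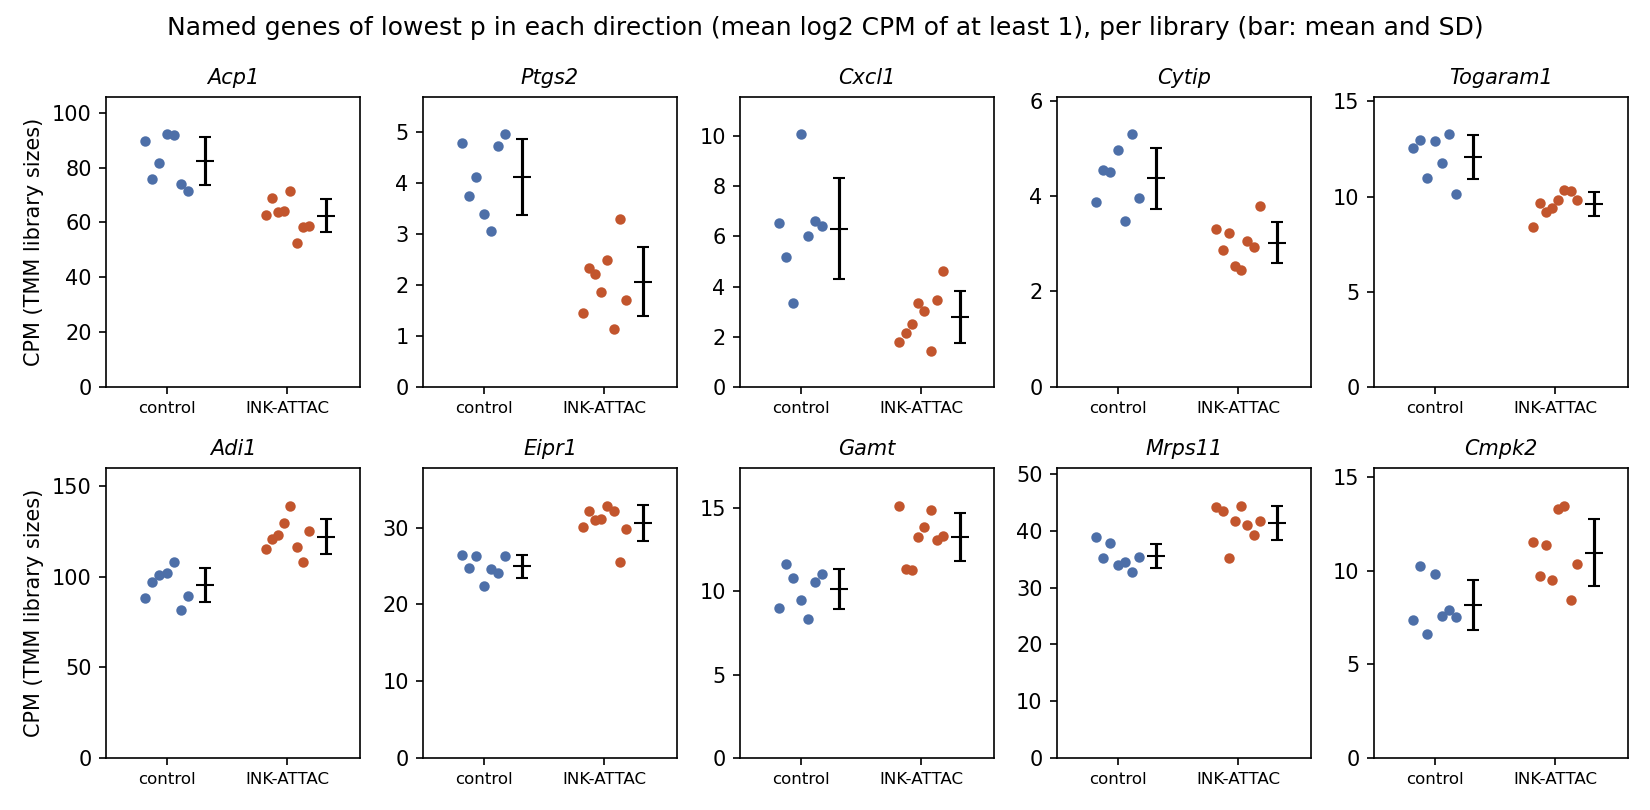
Level of the 5 genes of lowest p among those lower (top) and higher (bottom) in INK-ATTAC libraries, of genes with a mean log2 CPM of at least 1 and no predicted or clone-based name, in CPM on TMM library sizes. Each point is 1 library (7 control, blue; 8 INK-ATTAC, orange) and the bar gives the mean and SD. Ptgs2 averaged 4.11 CPM in controls and 2.06 CPM in INK-ATTAC libraries, and no gene shown passed the edgeR threshold.

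With edgeR's quasi-likelihood test, 0 genes had an adjusted p under 0.05, and the lowest adjusted p was 0.515. At an unadjusted p under 0.05 there were 745 genes, 396 higher and 349 lower, where 900 would be called if no gene differed. The biological coefficient of variation was 0.265 and the median log2 fold change of all genes tested was -0.00097. DESeq2 called 6 genes and had 758 at an unadjusted p under 0.05, limma-voom called 0 with 781, and limma-voom with sample quality weights called 2 with 1068. The 6 genes from DESeq2 were Cxcl1, Ptgs2, Acp1, Zfp184 and Cd300e, all lower, and Adi1, which was higher. Zfp184 (edgeR log2 fold change -0.69, adjusted p = 0.546) and the myeloid receptor gene Cd300e (-1.39, adjusted p = 0.573) lie outside the rule for named genes and were chosen after their values were seen. With edgeR, 0 genes passed in the libraries with low Xist alone (909 at an unadjusted p under 0.05) and 0 in those with high Xist alone (730).

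The authors' deposited table called 3 genes at its adjusted p under 0.05, 2 higher and 1 lower in INK-ATTAC mice. In the authors' deposited table these were Gm6472, with a log2 fold change of 1.01 and an adjusted p of 0.0126, Ptgs2 with -1.18 and 0.0267, and Adi1 with 0.39 and 0.0471. Gm6472 is a transcribed processed pseudogene on chromosome X from 152909505 to 152910155 (GRCm38), so its counts can include reads of the parent gene and its value is uncertain. In the edgeR fit it gave a log2 fold change of 0.77 (SE 0.19, adjusted p = 0.955). It averaged 13.9 ± 5.75 CPM in controls (SD, n = 7) and 23.5 ± 2.63 CPM in INK-ATTAC libraries (SD, n = 8), and the highest control library, at 22.9 CPM, lay inside the INK-ATTAC range of 20.6 to 28.3 CPM. Fold changes of the authors' deposited table correlated at 0.849 with those of edgeR across genes, which are not independent replicates. limma-voom with sample quality weights on genes over 1 CPM in 7 libraries called the same 3 genes.

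Several of the named genes lie near each other on chromosome 12. Acp1 (30893326 to 30911589), Adi1 (28675231 to 28682175), Eipr1 (28751803 to 28869865) and Cmpk2 (26469204 to 26479837; all GRCm38) fall between 25 and 32 Mb, a region chosen after their values were seen. Of the 29 genes tested there, 7 had an unadjusted p under 0.05, 4 of them higher and 3 lower. The further 3 were Sox11 (log2 fold change -0.64, SE 0.20), Tmem18 (0.25, SE 0.08) and Sh3yl1 (-0.26, SE 0.11). In the annotation Acp1 overlaps the end of Alkal2, whose log2 fold change was 0.02 (SE 0.26), and reads of overlapping genes may be counted for either.

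**Figure D2:**
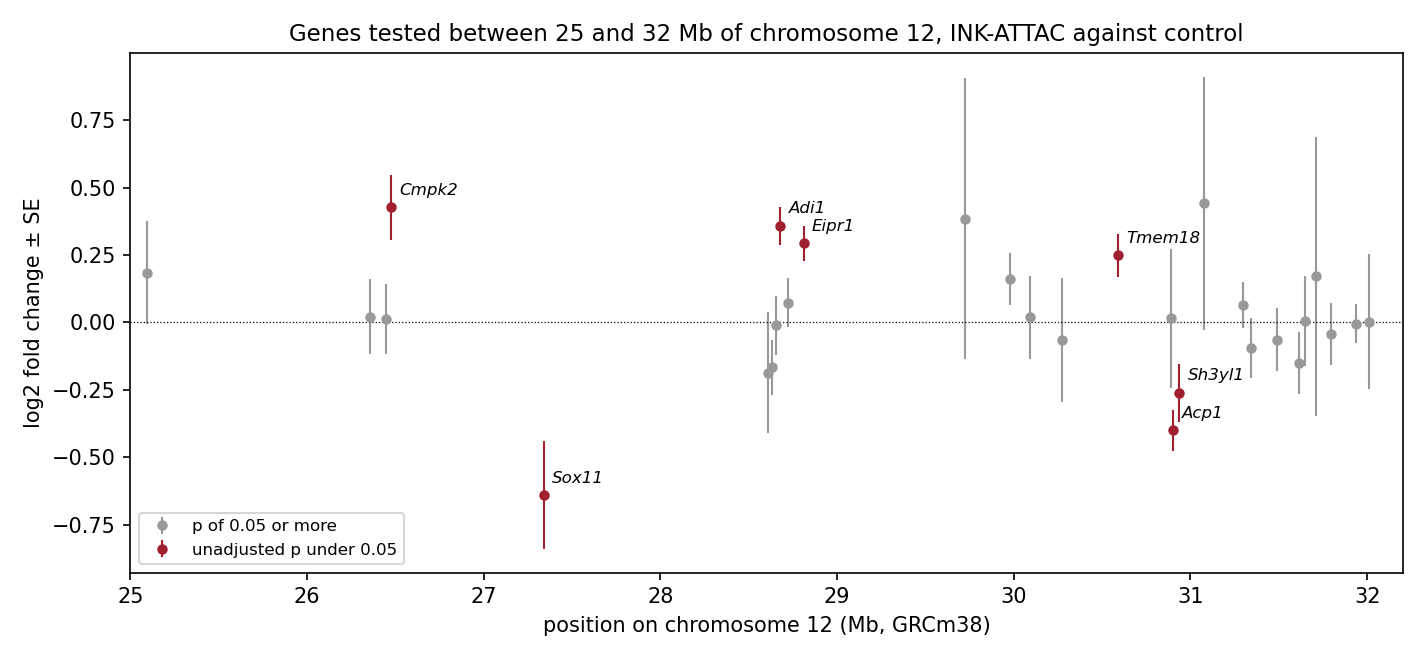
Log2 fold change with its standard error (edgeR, INK-ATTAC against control, 8 against 7 libraries) of the 29 genes tested between 25 and 32 Mb of chromosome 12, at the midpoint of each gene in GRCm38. The standard error was derived from the fold change and its F statistic. The 7 genes at an unadjusted p under 0.05 are named and drawn in red, 4 above and 3 below 0, and the others are grey.

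Gene lists written before the data were examined were tested as sets with limma camera. Of 50 lists, 14 passed with the preset correlation between genes of 0.01, 5 higher and 9 lower in INK-ATTAC libraries. In 99 other splits of the libraries into 7 and 8, a median of 15 lists passed, with 4 the fewest and 27 the most. Passing at the preset correlation therefore does not by itself set the groups apart. With an estimated correlation 0 of the 14 held, and fry, which asks whether a list's genes move one way on balance, called 0 lists. No member of any list passed over all genes tested. An exact permutation test of the mean level of each list also called 0 lists after adjustment.

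The lists of immediate early, NF-kB, unfolded protein response, autophagy and apoptosis genes were lower with the preset correlation. Immediate early genes, transcribed within minutes of a stimulus, had a median log2 fold change of -0.31, with 19 of 22 members lower (adjusted p = 4.8e-07, and adjusted p = 0.836 with an estimated correlation). Among them were Egr1 (-0.97), Ier2 (-0.48), Btg2 (-0.35) and Ier3 (-0.30). The list averaged 2.99 ± 0.29 log2 CPM in controls (SD, n = 7) and 2.63 ± 0.51 in INK-ATTAC libraries (SD, n = 8; exact permutation test, p = 0.127). The NF-kB inflammatory list had a median of -0.14 with 23 of 29 members lower (adjusted p = 0.0016, and adjusted p = 0.836 with an estimated correlation). Ptgs2 and Cxcl1, both in that list, were the 2 members with an adjusted p under 0.05 adjusted over the list alone, and Il1b (-0.88) and the adhesion molecule gene Vcam1 (-0.32) followed. The unfolded protein response list had 17 of 24 members lower, with a median of -0.06 (adjusted p = 0.0065, and adjusted p = 0.394 with an estimated correlation), among them the chaperone genes Dnajb9 (-0.23), Hsp90b1 (-0.18) and Canx (-0.14). Autophagy genes were lower in 17 of 22 (median -0.04, adjusted p = 0.0344, and adjusted p = 0.394 with an estimated correlation), with Rb1cc1 at -0.21 and Map1lc3a, which went the other way, at 0.18. The mean autophagy level was 6.06 ± 0.03 log2 CPM in controls (SD, n = 7) and 6.01 ± 0.01 in INK-ATTAC libraries (SD, n = 8; exact permutation test, p = 0.0011, adjusted p = 0.0544). Apoptosis genes were lower in 20 of 27 (median -0.04, adjusted p = 0.0344, and adjusted p = 0.420 with an estimated correlation), among them Pmaip1 (-0.46) and the death receptor gene Tnfrsf10b (-0.18). With skeletal muscle level as a covariate, the immediate early (adjusted p = 0.0906), NF-kB (adjusted p = 0.774) and apoptosis lists (adjusted p = 0.343) no longer passed. Over all settings the adjusted p of each of these 3 ranged up to 0.994, from 1.4e-14, 1.5e-05 and 0.0080 in that order. With lens level as a covariate NF-kB (adjusted p = 0.0520) and apoptosis (0.110) also no longer passed. Autophagy no longer passed with rod level (adjusted p = 0.0575; 0.0077 to 0.404 over all settings), nor did the unfolded protein response with rod, muscle and lens levels together (0.0666; 9.5e-04 to 0.994).

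Within libraries of low Xist (3 control and 4 INK-ATTAC) the mean immediate early level differed by -0.69 log2 CPM between the groups. Within those of high Xist (4 and 4) it differed by -0.04. The mean NF-kB level differed by -0.38 and -0.09 in the same order. Tested as a list with camera at the preset correlation, immediate early genes gave an adjusted p of 1.4e-14 and 0.602. NF-kB genes gave 1.9e-05 and 0.602, so both lists passed only with low Xist. These p-values treat genes as nearly independent. The correlation estimated over all libraries was 0.48 for the immediate early and 0.30 for the NF-kB list. Neither an estimated correlation nor a permutation of the level was run within a class alone. The autophagy list also passed only with low Xist (adjusted p = 0.0304, and 0.404 with high Xist), and the unfolded protein response (0.176 and 0.0622) and apoptosis lists (0.152 and 0.252) passed in neither. The difference between the Xist classes was not past the threshold for any of the 5 lists (immediate early, exact permutation of group labels within each class, p = 0.163, adjusted p = 0.815 over 30 lists and genes). Heat shock chaperones, with 7 genes higher and 7 lower (median log2 fold change -0.0048, adjusted p = 0.583), did not pass. Antioxidant response genes were higher in 15 of 26 with a median of 0.02, while the test pointed lower (adjusted p = 0.974).

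With the preset correlation, lists of markers of neighbouring and blood-borne cells passed in both directions. All 13 lens markers were higher, with a median log2 fold change of 2.66 (adjusted p = 2.8e-05, and adjusted p = 0.836 with an estimated correlation), and 5 of them had an adjusted p under 0.05 adjusted over the list alone. The crystallin genes Crygb (3.69), Crygc (3.56), Cryba4 (3.07) and Crygd (3.02) led the list. All 21 skeletal muscle markers were also higher, with a median of 0.78 (adjusted p = 9.9e-13, and adjusted p = 0.577 with an estimated correlation), led by Tnnc2 (1.19), Acta1 (1.17), Ckm (1.09) and Atp2a1 (0.95). Rod photoreceptor markers were lower in 21 of 22 (median -0.26, adjusted p = 1.2e-04, and adjusted p = 0.861 with an estimated correlation), with Samd7 at -0.57, Rp1 at -0.38 and Nrl, a rod transcription factor, at -0.35. Cone markers were lower in 9 of 11 (median -0.11, adjusted p = 0.0344, and adjusted p = 0.836 with an estimated correlation). Mast cell markers were lower in 8 of 9 (median -0.30, adjusted p = 0.0097, and adjusted p = 0.836 with an estimated correlation), with Tpsb2 at -0.64 and Cpa3 at -0.58. INK-ATTAC 7 stood apart in this list, at -1.43 log2 CPM against 0.54 in the nearest library of its group. Without INK-ATTAC 7 (camera adjusted p = 0.367) or without control 3 (0.158) the mast cell list no longer passed. Erythrocyte markers were lower in 9 of 9 (median -0.44, adjusted p = 0.0247, and adjusted p = 0.860 with an estimated correlation), with Slc4a1 at -0.94 and Alas2 at -0.70.

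With low Xist alone the lens (adjusted p = 1.8e-08), rod (2.2e-04) and erythrocyte lists (1.9e-05) passed, and with high Xist alone they did not (0.316, 0.130 and 0.796), the erythrocyte list having turned. The mast cell list passed with high Xist (7.5e-05) and not with low Xist (0.787), and the cone list passed in neither (0.144 with low Xist and 0.340 with high Xist). Skeletal muscle markers passed in both classes. None of these lists differed between the Xist classes past the threshold (exact permutation within classes, lowest adjusted p = 0.815). With rod level as a covariate the cone (adjusted p = 0.704), mast cell (0.0795) and erythrocyte lists (0.112) no longer passed. With skeletal muscle level the lens (0.0523) and cone lists (0.188) did not. The cone list also did not pass with endothelial level (adjusted p = 0.0706) or with a block by title number (0.184). Over all settings the adjusted p of each of these lists reached 0.994, from 0.0055 for cone, 8.0e-08 for mast cell, 1.9e-05 for erythrocyte and 1.5e-27 for lens markers.

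The spread of these marker levels within groups was large. Lens markers averaged 0.30 ± 1.76 log2 CPM in controls (SD, n = 7) and 2.22 ± 2.62 in INK-ATTAC libraries (SD, n = 8; exact permutation test, p = 0.124). Skeletal muscle markers averaged 4.57 ± 0.97 and 5.42 ± 0.68 (n = 7 and 8; exact permutation test, p = 0.0695), and rod markers 4.93 ± 0.62 and 4.50 ± 1.03 (n = 7 and 8; exact permutation test, p = 0.369). RPE markers averaged 10.1 ± 0.10 in controls and 10.1 ± 0.11 in INK-ATTAC libraries, and as a list had a median of -0.03 and did not pass (adjusted p = 0.466). Mitf, a transcription factor of pigment cells, was the RPE marker of lowest p, with a log2 fold change of -0.33 and a p of 0.0571 adjusted over the list alone, outside edgeR's threshold.

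**Figure D3:**
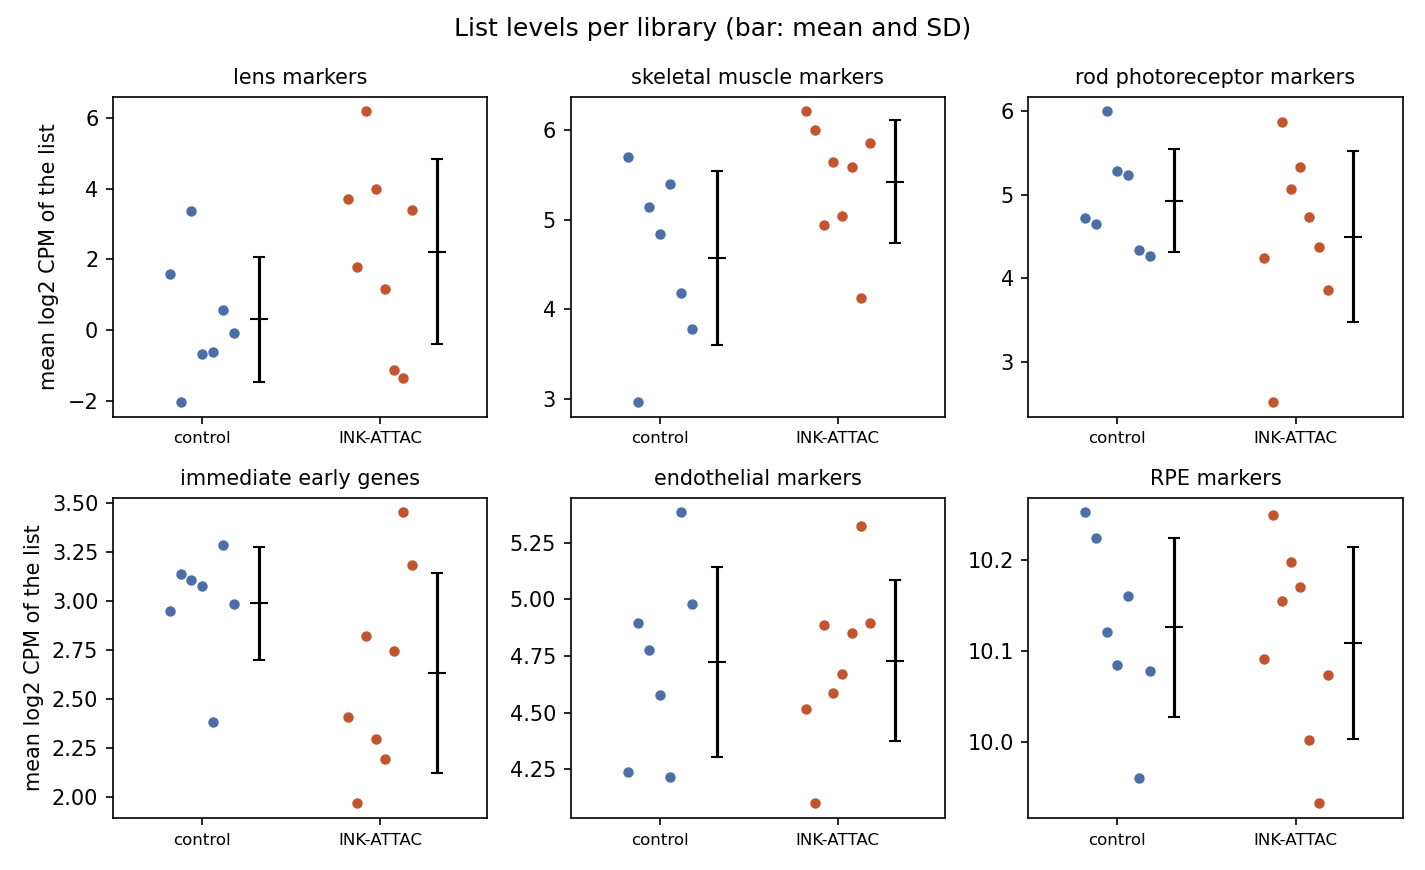
Mean log2 CPM of 6 marker or response lists in each library (7 control, blue; 8 INK-ATTAC, orange), with the mean and SD of each group as a bar. Lens levels averaged 0.30 in controls and 2.22 in INK-ATTAC libraries with an SD of 1.76 and 2.62, and the groups overlap in every panel.

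The lists of nuclear-encoded oxidative phosphorylation, glycolysis and cytosolic ribosomal protein genes were slightly higher with the preset correlation. Nuclear-encoded genes of oxidative phosphorylation were higher in 29 of 32, with a median log2 fold change of 0.07 (adjusted p = 1.1e-05, and adjusted p = 0.836 with an estimated correlation), among them Cox5a (0.34), Cyc1 (0.20), Ndufb8 (0.19) and Uqcrc1 (0.18). Glycolysis genes were higher in 17 of 21 (median 0.07, adjusted p = 0.0444, and adjusted p = 0.894 with an estimated correlation), with Pfkm at 0.32 and Ldha at 0.18. Cytosolic ribosomal protein genes were higher in 25 of 34, with a median of 0.05 (adjusted p = 0.0039, and adjusted p = 0.937 with an estimated correlation). With skeletal muscle level as a covariate, oxidative phosphorylation (adjusted p = 0.760) and ribosomal protein genes (adjusted p = 0.115) no longer passed and their direction turned, and glycolysis genes no longer passed (adjusted p = 0.531). With lens level glycolysis turned (adjusted p = 0.921) and ribosomal protein genes no longer passed (0.0520). With sex-linked level as a covariate glycolysis no longer passed (adjusted p = 0.0647). Over all settings tried the adjusted p of each of these lists reached 0.994, and its lowest was 1.5e-09 for oxidative phosphorylation, 6.5e-06 for ribosomal protein genes and 4.4e-04 for glycolysis. Glycolysis and ribosomal protein genes passed with high Xist (adjusted p = 4.4e-04 and 0.0108) and not with low Xist (0.377, with the direction turned, and 0.236). The difference between the Xist classes did not pass for either (exact permutation within classes, adjusted p = 0.815 for glycolysis and 0.945 for ribosomal protein genes). Mitochondrially encoded transcripts, which also serve oxidative phosphorylation, were lower in 9 of 13 (median -0.09, adjusted p = 0.434). Fatty acid oxidation genes were higher in 13 and lower in 11 (median 0.01, adjusted p = 0.944).

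**Figure D4:**
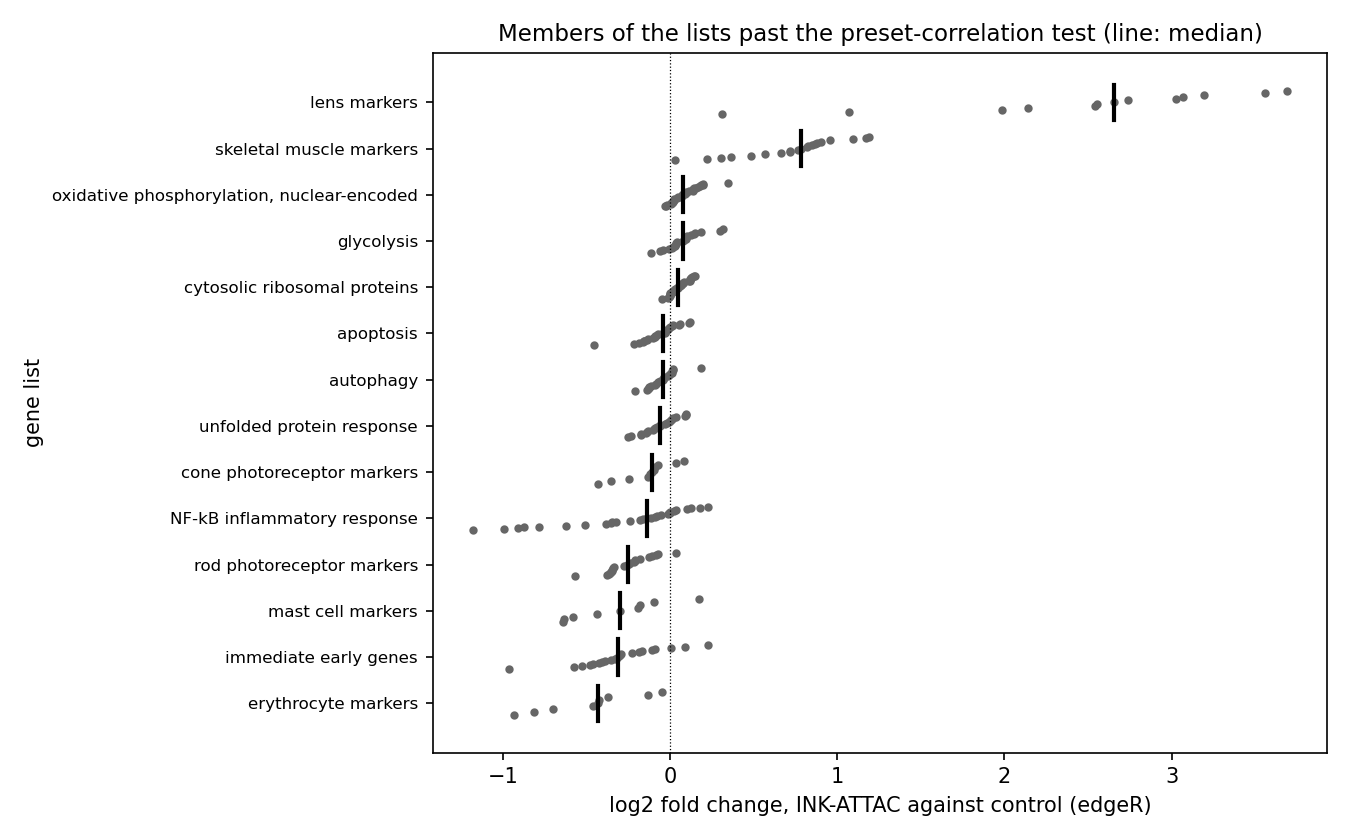
Log2 fold change (edgeR, INK-ATTAC against control, 8 against 7 libraries) of each tested member of the 14 lists that passed limma camera with the preset correlation. Each point is 1 gene and the black line is the list's median, which runs from -0.44 for erythrocyte markers to 2.66 for lens markers.

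The lists closest to the design did not pass. Senescence core genes and p53 targets had a median log2 fold change of -0.05, with 16 of 24 lower (adjusted p = 0.134), among them Btg2 (-0.35), Trp53inp1 (-0.28) and Mdm2 (-0.14). Senescence-associated secretory factors had a median of -0.03 with 26 of 47 lower (adjusted p = 0.393). Cxcl1 was the 1 member of that list under 0.05 adjusted over the list alone, and the chemokine genes Ccl4 (0.77) and Ccl3 (0.55) lay in the opposite direction to Il1b (-0.88). Cholesterol efflux genes had a median of 0.00 (adjusted p = 0.944), cholesterol synthesis and uptake genes of -0.03 (adjusted p = 0.199) and complement genes of -0.01 (adjusted p = 0.573). Macrophage and microglia markers were lower in 18 of 23, with a median of -0.04 (adjusted p = 0.240), and monocyte and neutrophil markers had a median of -0.14 (adjusted p = 0.199). Interferon response genes were higher in 26 of 35, with a median of 0.09 (adjusted p = 0.0925), and phagocytosis and lysosome genes were lower in 25 of 30, with a median of -0.05 (adjusted p = 0.131). Visual cycle genes had a median of -0.03 (adjusted p = 0.725).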

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

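The test of unequal tissue carry-over for lens, muscle and rod markers was chosen after the result was seen, as were that of carry-over for chromosome 12 and that of a secretory profile for Ptgs2 and Cxcl1. So were the exact permutation of list levels, the setting with quality weights and the stricter filter, the chromosome 12 region itself, and the counts over splits with equal Xist balance. The counts over all splits for edgeR, the lists and DESeq2, and the covariates for Ptgs2 and Cxcl1, were set before the results they measure were seen.

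Of 62 checks of single libraries against their group, 4 found a library far from the rest, where chance gives about 3.1. Eipr1 in INK-ATTAC 7, at 4.68 log2 CPM, was separated from the nearest library at 4.90 by 0.609 of the group's range. The immediate early list in control 5, at 2.38 log2 CPM against 2.95 in the nearest library, was separated by 0.629 of the range. The mast cell list in INK-ATTAC 7, at -1.43 against 0.54 log2 CPM, was separated by 0.572. The total count of INK-ATTAC 6, at 65065950 against 55011182 in the next library, was separated by 0.588 of the range.

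The number of genes at an unadjusted p under 0.05, 745, was reached by 44 of 100 splits of the libraries into 7 and 8, the real split included, and the highest of the others was 3201. The lowest p of the real split was reached by 22 of 100 splits. The 14 lists were reached by 58 of 100 splits, with 27 the highest of the others and a median of 15. The 6 genes of DESeq2 were reached by 18 of 100 splits (highest other 891), and the 3 genes of limma-voom with quality weights and the stricter filter by 7 of 100 (highest other 2462). Chance was not excluded for any of these counts. The splits did not keep the Xist balance of the groups, and 40 of the 100 happened to. Of these 40, the real split included, 21 reached the genes, 7 the lowest p, 22 the lists, 8 the DESeq2 count and 3 the quality weights count, so chance was not excluded there either. Splits with several times the real count point to a structure of the samples. Of the 5 splits with the most genes, 4 were those with the 4 largest differences in first principal component score, and the other, with 3146 genes, ranked 31 by that difference. The first component is by construction the axis along which these same libraries vary most. Its match with the splits is therefore not separate evidence of a structure.

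Genes of low p lay close together on chromosome 12, with 6 at an unadjusted p under 0.01 in a 5 Mb window from 26469204. A count as high in some window of the genome came from 23 of 100 splits, and 9 was the highest of the others, so chance was not excluded. The count was not adjusted for gene density, for the number of genes of low p in a split, or for neighbouring genes that vary together between libraries. It was 9 in a split with 3201 genes at an unadjusted p under 0.05, against 745 in the real split. A split with 613 such genes also reached 9, in a window on chromosome 6 from 68270485. The window of a split with 511 such genes, with a count of 6, began nearby at 68704508. Whether the genes of these windows vary together was not tested. The count therefore measures clustering only in part, and its rate over splits decides little for neighbours that vary independently. Carry-over of neighbouring tissue is argued against as the whole cause, because with rod, muscle and lens levels as covariates the median size of the folds of its 7 genes at an unadjusted p under 0.05 was 1.03 times that without. Single ratios averaged 0.907 (SE 0.098), with 4 of 7 under 1 and a lowest of 0.638 for Sh3yl1. A linked DNA difference between the groups, such as sequence around a transgene, may be a cause: in the 10 Mb on each side 5.56% of genes had an unadjusted p under 0.05, a share reached by 34 of 100 splits (highest other 15.3%), which leaves it open, since a short segment need not reach the flanks.

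Ptgs2 and Cxcl1 were lower in INK-ATTAC libraries. With the immediate early level as a covariate the log2 fold change of Ptgs2 was -0.91 (SE 0.22, from -0.999) and that of Cxcl1 -1.07 (SE 0.25, from -1.18), so the lower of their ratios was 0.909, which argues against the immediate early state at dissection as the whole cause. With macrophage, monocyte and neutrophil levels as covariates the lower ratio was 0.979. The macrophage and microglia list differed by 0.0051 log2 CPM between the groups and the monocyte and neutrophil list by -0.090. These covariates could therefore move the folds little. The values argue only against fewer cells, as these lists measure them, as the whole cause. A subset with other markers was not tested. Fewer cells with a senescence-associated secretory profile may be a cause, as the design would have it, but the rest of the secretory list had an unadjusted p-value of 0.421 in limma camera at the preset correlation, which decides nothing for a few lost cells. Chance among 17991 genes also stays open, as above.

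Lens and skeletal muscle markers were higher and rod markers lower in INK-ATTAC libraries. Within groups the members of each list moved together between libraries, with a lowest mean correlation of 0.680. Unequal carry-over of lens, eye muscle and retina at dissection predicts this, but it is not particular to carry-over. Cytosolic ribosomal protein genes, which mark no neighbouring tissue, gave 0.693, and RPE markers gave 0.247. The correlation therefore does not tell carry-over from other causes. No tested member of these lists is in another list, and among the abundant lens and muscle members were Cryaa (84.9 ± 192 CPM in controls, 336 ± 681 in INK-ATTAC libraries) and Acta1 (267 ± 167 and 602 ± 265; SD, n = 7 and 8). The lowest exact permutation p of the 3 list levels was 0.0695, so a chance division of these levels between the groups was not excluded. A biological difference in these tissues from the transgene was not tested.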

How the results depend on the processing

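Settings chosen after seeing the data were the lens, endothelial and combined covariates, the Xist subsets, robust estimation, quality weights with the stricter filter, and the list permutation. For the lists so was the sex-linked covariate. edgeR called 0 genes, and other settings called 6 (DESeq2), 2 (quality weights), 1 (1 surrogate variable) and 3 (quality weights with CPM above 1 in 7 libraries). The other 32 settings, leave-one-out fits included, gave 0 (0 to 0 leaving out a library). The 14 lists became 0 with an estimated correlation, 0 with fry, 0 by exact permutation and 9 in high-Xist libraries. Leaving out a library gave 9 (without control 3, and without INK-ATTAC 2) to 16. For Cdkn2a the pooled log2 ratio of -0.47 ranged from -1.88 (without INK-ATTAC 1) to -0.16 (without control 4) and was -0.42 with no filter. Settings on filtered genes gave it no value.

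Numbers shared between groups in the labels are not said to pair animals. Of 7 pairs by title number 4 correlated over 0.1, and 1 control correlated best with its own number. By description number these were 2 and 0. Both numberings follow the Xist class. By description number each pair shares that class, and by title number each does but pair 4, whose r was -0.10. Pair correlations and a block by number therefore also hold differences between the Xist classes. With a replicate block 0 genes were called by either number and 16 lists by title number. The cone list was not among these (camera adjusted p = 0.184).

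Values of 23 genes were followed over the settings, the sex-linked transcripts left out. Besides genes named by the rule they included Gm6472 and, chosen after seeing the data, Cd300e, Treml4, Adgre4, Zfp184, Tmem18 and Sox11. Of these values 758 kept direction and side of the threshold, 12 passed and 14 turned. Cd300e and Zfp184 gave 1 of the passes each. Among lists these were 250 kept, 115 no longer past the threshold and 13 turned; the cause was not tested beyond each covariate. The log2 fold change of Casp8 turned with quality weights (0.0028), with these and the stricter filter (0.0094) and with low Xist (0.059), and with 1 library left out ranged from -0.071 to 0.013 (without INK-ATTAC 7). Fkbp1a turned with low Xist (-0.015). Abca1 turned with muscle (0.030), lens (0.011) and 3 covariates (0.014) and high Xist (0.087), and with 1 library left out ranged from -0.13 to 0.0055 (without control 6). Abcg1 turned with muscle (0.155), 3 covariates (0.201) and high Xist (0.039), and Lyz2 with high Xist (0.026). With 1 library left out Abcg1 ranged from -0.24 (without INK-ATTAC 7) to -0.025 (without control 6) and Fkbp1a from 0.047 (without control 1) to 0.11 (without control 3), with no turn. Adjusted p of lists that turned with muscle were 0.760 (oxidative phosphorylation) and 0.115 (ribosomal). With lens they were 0.921 (glycolysis) and 0.175 (lens), with rod 0.807 (rod), with low Xist 0.377 (glycolysis) and with high Xist 0.796 (erythrocyte). With 3 covariates they were 0.888 (oxidative phosphorylation, glycolysis, rod), 0.9504 (cone), 0.367 (lens) and 0.583 (ribosomal). The lens, rod and muscle lists lose their call by construction when their own level is a covariate, alone or with the others. These cases are in the counts above and say nothing of how stable those lists are. With 1 library left out, some lists missed the threshold. They were NF-kB (adjusted p up to 0.103, without control 6), apoptosis (0.104; control 6, 7, INK-ATTAC 3), autophagy (0.158; control 1, 3, INK-ATTAC 3, 7), cone (0.217; control 3, 5, INK-ATTAC 1, 2, 6, 8), ribosomal (0.438; control 2, 6, 7, INK-ATTAC 1, 2, 5), erythrocyte (0.255; control 1, 3, 7, INK-ATTAC 2, 5), glycolysis (0.316; control 4 to 7, INK-ATTAC 1 to 5), mast cell (0.367; control 3, INK-ATTAC 7) and rod (0.140; control 3, INK-ATTAC 2).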

Other observations

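The relations between list levels in this part were chosen after seeing the data. The first principal component of the 15 libraries, with 18% of the variance, had a mean score of 4.52 ± 27.8 in controls (SD, n = 7) and -3.95 ± 28.6 in INK-ATTAC libraries (SD, n = 8; exact permutation test, p = 0.5681). Libraries with more endothelial transcripts held fewer RPE transcripts (n = 15, Pearson r = -0.77, permutation p = 0.00084, adjusted p = 0.00084; Spearman rho = -0.69, permutation p = 0.0056). Without the 2 libraries farthest from the median r was -0.65, and within groups it was -0.72 in controls and -0.83 in INK-ATTAC libraries.

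Endothelial level went with lower oxidative phosphorylation (n = 15, r = -0.88, permutation p = 3e-05, adjusted p = 4.5e-05; rho = -0.87, permutation p = 9e-05) and with higher collagen and basement membrane genes (n = 15, r = 0.90, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 3e-05; rho = 0.87, permutation p = 0.00013). Without the farthest 2 libraries r was -0.79 and 0.84. These 3 relations were the ones computed, so their adjusted p does not cover the choice among the 50 lists. Levels are relative to a library's TMM-scaled total. A larger share of choroid may therefore leave a smaller share for RPE, which was not tested. The levels of endothelial markers averaged 4.72 ± 0.42 log2 CPM in controls (SD, n = 7) and 4.73 ± 0.36 in INK-ATTAC libraries (SD, n = 8), so the axis ran within both groups.

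Treml4 and Adgre4, surface receptor genes of myeloid cells, were chosen after their values were seen. Treml4 averaged 2.05 ± 0.56 CPM in controls (SD, n = 7) and 1.155 ± 0.19 CPM in INK-ATTAC libraries (SD, n = 8), a log2 fold change of -0.83 (edgeR adjusted p = 0.716). Adgre4 gave -0.78 (adjusted p = 1.00) and Cd300e, another myeloid receptor gene, averaged 1.13 ± 0.37 and 0.43 ± 0.19 CPM (log2 fold change -1.39, adjusted p = 0.573). None passed with edgeR, and Cd300e passed with DESeq2 alone among the settings tried. The macrophage and microglia list (camera adjusted p = 0.240) and the monocyte and neutrophil list (0.199), written beforehand, did not pass.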
